A study of Mus musculus with 32 samples.

How the data were processed

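RNA from right cortex and right striatum of mice labelled Gpx1 knockout was hybridised to Illumina MouseRef-8 V2 bead arrays after sham surgery, or after 2 h of suture occlusion of the middle cerebral artery followed by 2, 8 or 24 h of reperfusion. Each of the 8 groups held 4 arrays, 32 in all, and the labels listed no wild-type array. The deposited growth protocol, however, says that male wild-type mice were employed, while sample titles, the genotype label and the treatment protocol say Gpx1 knockout. Per the file headers, the deposited probe profiles were exported by the authors from BeadStudio 3.3.7 without normalization, and they hold the mean bead signal of each probe as a linear intensity. The lowest deposited intensity values were above 0, so background had not been subtracted. The deposited detection column is a fraction, 1 minus the detection p. The authors' processed table holds, for each probe, a linear ratio to the mean of the 4 sham arrays of the same region, after a normalization between arrays that the labels do not name. These deposited ratio values were used as an alternative only, because they cannot compare the regions in sham animals.

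The profiles held 25697 probes. The deposited whole-series raw table carried the same signals, but under the mirrored replicate number of the same group (1 exchanged with 4, and 2 with 3), and was used only for probe identifiers. Replicate numbers here are those of the profiles. Current mouse gene names came from the accession for 23876 probes, from the symbol for 728 and from a synonym for 709, and 384 probes kept the name in the file, which gave 17877 names. The array codes in the sample descriptions were taken to name slides, which the labels do not state. By these codes each slide carried 4 arrays of this series, the sham, 2 h, 8 h and 24 h samples of one region. The replicate number was therefore the slide, each of the 8 slides held every group of its region, and 0 slides held both regions. The place on the slide was the same for every array of a group, so place and group cannot be told apart.

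Signals were background-corrected, quantile-normalized over all 32 arrays and put on a log2 scale with neqc in limma 3.58.1 (R 4.3.3 with data.table in version 1.17.8), with an offset of 16. Probes with a detection p under 0.01 on at least 4 of 32 arrays were kept, which left 12758 probes. Each gene was represented by its probe with the highest mean signal, which gave 9475 genes. An 8-group linear model (lmFit and eBayes) gave each log2 difference with its standard error (SE), and p was adjusted by the Benjamini-Hochberg method over all genes of a comparison, with 0.05 as the threshold. The limma, camera and fry tests were two-sided. With 4 arrays per group, the number of arrays limits the precision. Comparisons were each reperfusion time against sham within a region, successive times within a region, the difference between regions in the response at each time, and sham striatum against sham cortex. A gene counted as detected on an array if any of its probes was, even where the probe used was not. Where a gene was detected on 0 arrays of a group, its fold is a lower bound. Each array's value was first raised to at least the lowest detected log2 signal on that array, 5.57 to 5.97, and the difference of group means was then taken. Where a gene was detected on 1 to 3 arrays, the fitted fold is given and rests in part on background.

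The 33 gene lists, the comparisons, the tests, the rule for naming genes and all alternatives except one were chosen before the data were examined. For each comparison with sham, the rule took the 8 highest and 6 lowest log2 changes among genes that passed and whose reperfusion arrays did not overlap the sham arrays, leaving out clone names, and up to 3 members per list with the largest absolute change. For time steps and region differences it took the 4 highest and 4 lowest. Gpx1 was taken in every comparison. A gene may belong to more than 1 list. Lists with at least 5 measured members were tested with camera in limma at a preset inter-gene correlation of 0.01, with p adjusted over all lists and the 6 comparisons with sham, and separately over all lists and the 3 region differences. Of the 33 lists, 31 were tested; lymphocyte markers (3 measured) and blood haemoglobin and erythroid markers (4 measured) were too short. Each list's counts were also taken with p adjusted over the list alone. Medians of a list per slide compare each reperfusion array with the sham array of its own slide.

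Alternatives were the slide as a block, scaling to the 75th percentile, no background correction, the authors' processed values, no filter on detection, detection on all 4 arrays of a group, each region normalized and fitted alone, eBayes with a trend and robust spread, array weights, and all detected probes. Further ones were same-numbered cortex and striatum arrays as one animal (region differences), camera with an estimated correlation, and leaving out each of the 32 arrays in turn. The fry test was added after the data were seen. It tests whether the genes of a list move on balance one way and does not compare them with other genes. Groups were also split in every other way into sets of 4 and refitted, with 35 splits for 2 groups, and 100 drawn with a fixed seed for region differences. For these, whole slides were also exchanged between regions with the slide as a block, in 35 splits.

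The procedure was tested on simulated arrays. Each gene was drawn as independent normal noise around its real mean, with its real spread within groups, and changes were then added. Simulated genes did not vary together and slides had no effect, so the list tests were not tried under such conditions. In cortex at 24 h, 59.7% of genes raised or lowered 1.5-fold were recovered (40 of 67), 94% at 2-fold (63 of 67) and 100% at 4-fold (66 of 66), with 8 unchanged genes called. For the region difference at 24 h the recovered shares were 25.4%, 82.1% and 100%, with 4 unchanged genes called. A list of 22 genes raised 1.5-fold was called by camera (p = 1.73e-64, and p = 1.79e-14 with an estimated correlation) and by fry (p = 3.81e-17), and camera called 0 of 31 other lists. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Of the 25697 probes, those under the detection filter were left out of the model, as were all columns of the profiles other than signal and detection.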

Results

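Gene expression was measured in the cortex and striatum of mice labelled Gpx1 knockout, which by that label lack glutathione peroxidase 1, an enzyme that reduces hydrogen peroxide. A suture blocked the middle cerebral artery for 2 h, a model of stroke, and tissue was taken 2, 8 or 24 h after blood flow returned, or after sham surgery. Each of the 8 combinations of region and condition had 4 arrays. The median raw signal per array was 60.1 to 92.4, and 10701 to 11935 of 25697 probes were detected (41.6% to 46.4%). Pearson's r between arrays of a group, across genes, was 0.9564 to 0.9941. The first principal component held 40.2% of the variance and parted the regions (cortex -30.3 to -8.9, striatum 14.9 to 31.1). The second held 21.5% and parted sham arrays (-27.6 to -15.0) from reperfusion arrays (-10.6 to 37.4). On it, cortex 24 h replicate 1 lay at -3.9 against 18.0 to 37.4 for the other arrays of its group, and cortex 8 h replicate 4 lay at -0.5 against 12.5 to 15.4. In what follows, log2 changes are given with their SE from limma and n = 4 arrays per group.

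Gpx1, the gene named in the genotype label, was detected on 32 of 32 arrays through its 1 probe (1980301), and its group means lay at the 85th to 91.3th percentile of probes. This checked what the array reports for the targeted gene. In cortex the mean log2 signal was 8.85 ± 0.05 in sham, 9.21 ± 0.16 at 2 h, 9.74 ± 0.63 at 8 h and 9.29 ± 0.32 at 24 h (SD, n = 4). In striatum it was 9.27 ± 0.11, 9.38 ± 0.12, 9.64 ± 0.20 and 9.53 ± 0.26 (SD, n = 4). Gpx1 rose in cortex at 8 h by 0.88 ± 0.19, or 1.85-fold (adjusted p = 0.00241), on 4 of 4 slides. Without cortex 8 h replicate 1 the change was 0.65 (adjusted p = 0.0126). The changes that did not pass were 0.35 (adjusted p = 0.293) and 0.44 (0.0803) in cortex at 2 and 24 h, and 0.12 (0.768), 0.37 (0.16) and 0.27 (0.308) in striatum at 2, 8 and 24 h. Cortex at 24 h passed without cortex 8 h replicate 1 (adjusted p = 0.0372), cortex 8 h replicate 4 (0.0302) or cortex 24 h replicate 1 (0.0263), and with array weights (0.0155). Striatum at 8 h passed with each region fitted alone (0.0449) and with array weights (0.0498). No wild-type array was available, and the place of the probe relative to the part of the gene that a knockout deletes is not known from the files.

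**Figure D1:**
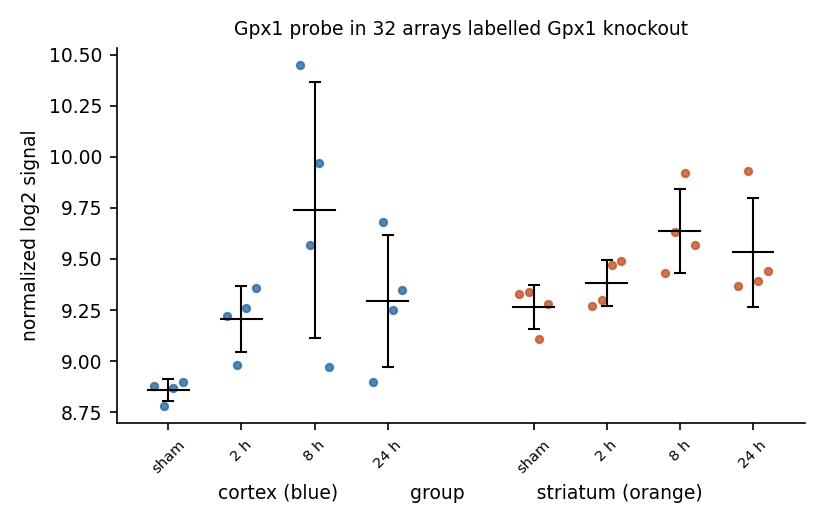
Normalized log2 signal of Gpx1 on each array (dots) with the group mean and SD, for sham and 2, 8 and 24 h of reperfusion in cortex and striatum (n = 4 arrays each). The probe was detected on 32 of 32 arrays, and the group mean was highest in cortex at 8 h (9.74).

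The comparison of cortex at 2 h with sham asked which transcripts differed soonest after blood flow returned. Hspa1a, an inducible heat shock protein, rose 16.8-fold (log2 4.07 ± 0.97, adjusted p = 0.0148). Socs3, a feedback inhibitor of cytokine signalling, rose 6.52-fold (2.71 ± 0.53, adjusted p = 0.00386). Timp1, an inhibitor of matrix metalloproteinases, rose 5.35-fold (2.42 ± 0.45, adjusted p = 0.00281) over a cortex sham level detected on 1 of 4 arrays, and Depp1, a target of FOXO transcription factors, rose at least 4.77-fold (adjusted p = 4.97e-05). Among genes that fell were Slc40a1, the iron exporter ferroportin (-1.08 ± 0.19, adjusted p = 0.0016), Nkx2-2, a transcription factor of the oligodendrocyte lineage (-1.14 ± 0.24, adjusted p = 0.0066), and Sox9, an astrocyte transcription factor (-0.78 ± 0.15, adjusted p = 0.00306). A second Nkx2-2 probe changed by -0.26 (adjusted p = 0.338).

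Of the 25 measured immediate early genes, 11 rose, 0 fell and 14 did not pass (14 rose adjusted over the list alone), with a median of 1.06 and slide medians of 0.16 to 1.30. Fosb, an activity-induced transcription factor, rose 5.12-fold and Zfp36, which destabilises cytokine mRNAs, rose 4.24-fold. Camera gave adjusted p = 3.06e-11 for this list, and adjusted p = 0.521 with an estimated correlation. Of 18 cholesterol synthesis genes, 8 rose, 0 fell and 10 did not pass (10 rose adjusted over the list alone), with a median of 0.41 (adjusted p = 6.6e-10, and adjusted p = 0.465 with an estimated correlation). Examples are Mvd, an enzyme of the mevalonate pathway (2.46-fold), and Stard4, a sterol carrier (1.94-fold). Of 22 glucocorticoid response genes, 11 rose, 2 fell and 9 did not pass (13 rose and 2 fell adjusted over the list alone), with a median of 0.54 (adjusted p = 2.95e-07, and adjusted p = 0.465 with an estimated correlation). They include Angptl4, an inhibitor of lipoprotein lipase (2.66-fold), Ddit4, an inhibitor of mTOR (2.41-fold), and Cdkn1a, the cell cycle inhibitor p21 (2.39-fold). Of 16 genes of NF-kB feedback and innate signalling, 4 rose, 0 fell and 12 did not pass (8 rose adjusted over the list alone; adjusted p = 2.09e-07, and adjusted p = 0.521 with an estimated correlation).

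Of 19 oligodendrocyte and myelin markers, 4 rose, 0 fell and 15 did not pass in cortex at 2 h (8 rose adjusted over the list alone), with a median of 0.32 (adjusted p = 3.33e-06, and adjusted p = 0.521 with an estimated correlation). Opalin, an oligodendrocyte membrane protein, rose 2.31-fold (adjusted p = 0.014), which did not pass without cortex 2 h replicate 2 (adjusted p = 0.0641). Mal, a protein of myelin membranes, rose 1.44-fold (adjusted p = 0.0278), but not without any 1 of sham replicates 1, 2, 3 and 4 (0.0607, 0.0575, 0.0708 and 0.0542) or 2 h replicates 2 and 3 (0.128 and 0.0714). A second Mal probe changed by 0.32 (adjusted p = 0.297). Ugt8a, an enzyme that makes myelin lipids, rose 1.42-fold (adjusted p = 0.0426), but not without any 1 of sham replicates 1, 2, 3 and 4 (0.0663, 0.0525, 0.103 and 0.113) or 2 h replicates 1, 2 and 3 (0.0711, 0.167 and 0.0857). Of 26 cytokines and chemokines, 2 rose, 0 fell and 24 did not pass (5 rose adjusted over the list alone; adjusted p = 0.00079, and adjusted p = 0.598 with an estimated correlation). Ccl4, a chemokine that attracts monocytes and lymphocytes, rose at least 11.9-fold (adjusted p = 0.0181), and did not pass without cortex 2 h replicate 3 (adjusted p = 0.061) or on its second probe (0.0672). Of 22 unfolded protein and integrated stress response genes, 2 rose, 0 fell and 20 did not pass (5 rose adjusted over the list alone; adjusted p = 0.00188, and adjusted p = 0.571 with an estimated correlation). Of 24 heat shock proteins and cochaperones, 1 rose, 0 fell and 23 did not pass (1 adjusted over the list alone; adjusted p = 0.0211, and adjusted p = 0.619 with an estimated correlation), a call lost without cortex 2 h replicate 4 (adjusted p = 0.0798). Of 28 hypoxia and glycolysis genes, 2 rose, 0 fell and 26 did not pass (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.0761, and adjusted p = 0.521 with an estimated correlation). Among them Slc2a1, the glucose transporter of the blood-brain barrier, rose 1.59-fold (adjusted p = 0.00062). The 4 measured blood haemoglobin and erythroid markers, too few for a list test, had a median of 2.14, with 1 that rose, 0 that fell and 3 that did not pass (3 rose adjusted over the list alone).

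Limma called 441 genes in cortex at 2 h, 209 higher and 232 lower, of which 438 had the same direction on 4 of 4 slides. In 415 of the 441 the arrays of the groups did not overlap, which fixes this direction. Here and below, such counts follow largely from the choice of genes on the same arrays and are no separate evidence. By at least 2-fold, 44 were higher and 7 lower (30 and 1 without background correction). With the authors' values, where the median change of all genes was -0.133 and was not subtracted, 154 genes were called higher and 1854 lower. Array weights gave 1660 genes. Leaving out 1 array gave 210, 211, 283 and 290 genes without sham replicates 1, 2, 3 and 4, and 173 and 174 without 2 h replicates 2 and 3. No camera call in any comparison with sham held with an estimated correlation, while fry called 7 lists higher and 0 lower here against 12 and 0 by camera.

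The cortex at 8 h was compared with sham to follow the response into its middle phase. Several reactive astrocyte and NF-kB feedback genes rose, and several markers of microglia and neurons fell. Ccl4 rose at least 17.5-fold (adjusted p = 0.00241), or by log2 3.54 on its second probe (adjusted p = 0.00804), and Cxcl1, a neutrophil chemoattractant, at least 6.3-fold (adjusted p = 0.0031). Timp1 rose 10.7-fold (log2 3.42 ± 0.45, adjusted p = 5.5e-05), and Lcn2, an iron-binding protein of reactive astrocytes, 8.48-fold (3.08 ± 0.50, adjusted p = 0.000255). Gpr34, a microglial receptor, fell, to a level at least 2.23-fold lower (adjusted p = 0.000135), as did P2ry12, the purine receptor of resting microglia (-1.52 ± 0.26, adjusted p = 0.000331).

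Of 22 reactive astrocyte genes, 12 rose, 0 fell and 10 did not pass in cortex at 8 h (15 rose adjusted over the list alone), with a median of 0.91 and slide medians of 0.28 to 1.55 (adjusted p = 2.43e-08, and adjusted p = 0.54 with an estimated correlation). Of 22 glucocorticoid response genes, 13 rose, 1 fell and 8 did not pass (15 rose and 2 fell adjusted over the list alone), with a median of 0.75 (adjusted p = 1.6e-07, and adjusted p = 0.465 with an estimated correlation). Angptl4 rose 5.33-fold and Cdkn1a 3.99-fold. Of 16 NF-kB feedback and innate signalling genes, 10 rose, 0 fell and 6 did not pass (13 rose and 1 fell adjusted over the list alone; adjusted p = 4.6e-07, and adjusted p = 0.521 with an estimated correlation). Of 12 endothelial activation and adhesion genes, 7 rose, 0 fell and 5 did not pass (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.000702, and adjusted p = 0.571 with an estimated correlation). Ch25h, which makes an oxysterol that regulates immune cells, rose 6.07-fold. Of 25 p53 targets and apoptosis genes, 8 rose, 2 fell and 15 did not pass (9 rose and 2 fell adjusted over the list alone; adjusted p = 0.00344, and adjusted p = 0.521 with an estimated correlation). Fas, a death receptor, rose 2.34-fold and Pmaip1, which promotes apoptosis, at least 1.7-fold. Hmox1, which degrades heme, rose at least 2.65-fold (adjusted p = 0.0106).

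Of 22 microglia markers in cortex at 8 h, 3 rose, 9 fell and 10 did not pass (5 rose and 9 fell adjusted over the list alone). Camera did not call this list (median -0.14, adjusted p = 0.0619, and adjusted p = 0.692 with an estimated correlation). It passed without cortex sham replicate 1 (adjusted p = 0.0441), cortex 8 h replicate 2 (0.0178) or 3 (0.0309), with no filter on detection (0.0446) and with all detected probes (0.0288). Cx3cr1, the fractalkine receptor of microglia, fell by 1.03 ± 0.21 on the log2 scale (adjusted p = 0.00151). Of 18 cortical projection neuron markers, 0 rose, 7 fell and 11 did not pass (9 fell adjusted over the list alone), with a median of -0.49 (adjusted p = 0.00197, and adjusted p = 0.521 with an estimated correlation). Cux1, a transcription factor of upper-layer neurons, fell by 0.74 ± 0.14 and Slc30a3, the zinc transporter of synaptic vesicles, by 0.78 ± 0.19. Of 18 striatal projection neuron markers, 0 rose, 3 fell and 15 did not pass in cortex too (3 fell adjusted over the list alone; median -0.42, adjusted p = 0.0215, and adjusted p = 0.728 with an estimated correlation). That call was lost without cortex 8 h replicate 1 (adjusted p = 0.21) and with the authors' values (0.0529). Of 27 pan-neuronal and synaptic markers, 0 rose, 5 fell and 22 did not pass (5 fell adjusted over the list alone; adjusted p = 0.00694, and adjusted p = 0.598 with an estimated correlation), among them Gria2, an AMPA receptor subunit (-0.68 ± 0.12). Of 21 endothelial and blood-brain barrier markers, 6 rose, 5 fell and 10 did not pass, with the same counts adjusted over the list alone (median 0.06, adjusted p = 0.661, and adjusted p = 0.913 with an estimated correlation).

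In cortex at 8 h limma called 1917 genes, 908 higher and 1009 lower (536 and 2035 with the authors' values), and 1779 had the same direction on 4 of 4 slides. The counts at 2-fold or more were 117 higher and 33 lower, against 74 and 8 without background correction and 61 and 17 with the authors' values. Without sham replicate 2 the count was 1148, without 8 h replicate 3 it was 1164, and without 8 h replicate 4 the count at 2-fold or more was 233. On 8 h replicate 2, Pmch and Hcrt, neuropeptide precursors of the hypothalamus looked at after their values were seen in striatum, read 9.71 and 7.78 against 4.75 to 5.76 and 4.70 to 4.88 on the other arrays of the group. Camera called 13 lists higher and 3 lower (10 lists without 8 h replicate 1), and fry 9 and 2.

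**Figure D2:**
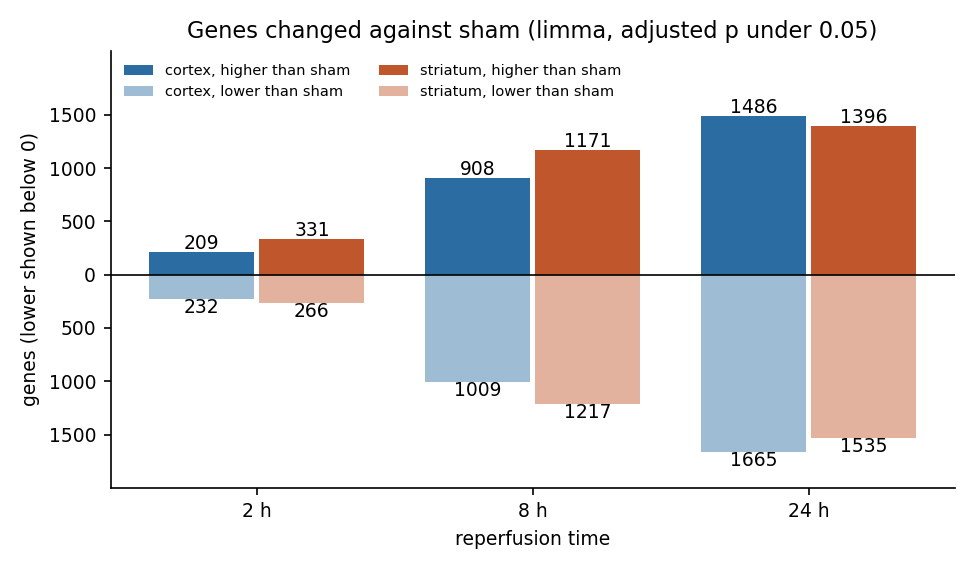
Number of genes higher and lower than sham (bars, adjusted p under 0.05, limma) at 2, 8 and 24 h of reperfusion in cortex and striatum, n = 4 arrays per group. Counts were 441, 1917 and 3151 in cortex and 597, 2388 and 2931 in striatum.

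The comparison of cortex at 24 h with sham addressed the state of the tissue a day after occlusion. Timp1 rose 18.4-fold (log2 4.20 ± 0.45, adjusted p = 3.91e-07), and Lgals3, a galectin of phagocytic cells, at least 12.8-fold (adjusted p = 2.43e-05). Ccl12, a monocyte chemoattractant, rose 14.5-fold (3.86 ± 0.65, adjusted p = 6.81e-05), Serpina3n, a protease inhibitor of reactive astrocytes, 8.87-fold (3.15 ± 0.39, adjusted p = 2.34e-06), and Fcgr4, an antibody receptor of myeloid cells, at least 4.46-fold (adjusted p = 3.25e-07). Syndig1l, a transmembrane protein related to a synapse differentiation factor, fell by 2.20 ± 0.28 (adjusted p = 2.97e-06), and Siglech, a lectin of microglia, by 1.37 ± 0.17 (adjusted p = 2.96e-06). A second Siglech probe changed by -0.27 (adjusted p = 0.214). The sham level of Timp1 was detected on 1 of 4 arrays.

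Of 22 reactive astrocyte genes, 19 rose, 0 fell and 3 did not pass in cortex at 24 h (20 rose adjusted over the list alone), with a median of 1.27 and slide medians of 0.08 to 2.26 (adjusted p = 1.88e-09, and adjusted p = 0.521 with an estimated correlation). Of 26 matrix remodelling and wound genes, 19 rose, 2 fell and 5 did not pass (21 rose and 2 fell adjusted over the list alone; adjusted p = 6.23e-07, and adjusted p = 0.561 with an estimated correlation). Mmp3, a matrix metalloproteinase, rose at least 2.57-fold. Of 17 interferon-stimulated genes, 13 rose, 0 fell and 4 did not pass (14 rose adjusted over the list alone), with slide medians of -0.24 to 1.56 (adjusted p = 5.67e-05, and adjusted p = 0.571 with an estimated correlation). Ifitm3, which blocks entry of viruses, rose 2.54-fold (adjusted p = 0.00186) with this direction on 3 of 4 slides. Of 13 neutrophil and monocyte markers, 9 rose, 0 fell and 4 did not pass (9 rose adjusted over the list alone), with slide medians of 0.23, 1.48, 0.34 and 2.58 (adjusted p = 0.00028, and adjusted p = 0.571 with an estimated correlation). S100a8, a subunit of calprotectin, had a mean 10.7-fold above sham, but its arrays overlapped. It read 6.04, 12.15, 7.65 and 11.58 at 24 h against 5.48, 7.74, 5.06 and 5.48 in sham. Sham replicates 1, 3 and 4 lay below the lowest detected signal of their arrays (5.71, 5.86 and 5.79), so the fold rests in part on background. Of 21 NRF2 targets, 7 rose, 0 fell and 14 did not pass (7 rose adjusted over the list alone; median 0.28, adjusted p = 0.00362, and adjusted p = 0.521 with an estimated correlation). Hmox1 rose at least 4.13-fold and Pgd, an enzyme of the pentose phosphate pathway, 1.57-fold.

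Enzymes that remove peroxide and superoxide, a group joined to the enzyme in the label by function, were 5 higher and 0 lower among 21 measured at 24 h in cortex. The other 16 did not pass (5 rose adjusted over the list alone). They include Prdx1 and Prdx3, peroxiredoxins of cytosol and mitochondria, at 1.47-fold (0.56 ± 0.11, adjusted p = 0.000487) and 1.38-fold (0.46 ± 0.10, adjusted p = 0.000657). Camera did not call the list (median 0.08, adjusted p = 0.173, and adjusted p = 0.677 with an estimated correlation), though it did without cortex 24 h replicate 1 (adjusted p = 0.0442). Of 27 pan-neuronal and synaptic markers, 0 rose, 12 fell and 15 did not pass (1 rose and 12 fell adjusted over the list alone; median -0.24, adjusted p = 0.00521, and adjusted p = 0.598 with an estimated correlation). Syn1, a protein of synaptic vesicles, fell by 0.78 ± 0.13, while a second Syn1 probe changed by 0.08 (adjusted p = 0.736). Of 18 cortical projection neuron markers, 0 rose, 9 fell and 9 did not pass (9 fell adjusted over the list alone; median -0.44, adjusted p = 0.0158, and adjusted p = 0.571 with an estimated correlation). That call was lost without cortex 24 h replicate 2 (adjusted p = 0.0508). Cux2 fell by 1.11 ± 0.15 and Cux1 by 1.06 ± 0.14, or by 0.59 on its second probe (adjusted p = 0.0017). Of 18 striatal projection neuron markers, 0 rose, 8 fell and 10 did not pass in cortex (8 fell adjusted over the list alone), with a median of -0.72 and slide medians of -1.17 to 0.22 (adjusted p = 0.00733, and adjusted p = 0.696 with an estimated correlation). Of 13 GABAergic interneuron markers, 0 rose, 3 fell and 10 did not pass (3 fell adjusted over the list alone; adjusted p = 0.213, and adjusted p = 0.677 with an estimated correlation), with adjusted p = 0.0427 with no filter on detection.

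Of 21 endothelial and blood-brain barrier markers, 10 rose, 2 fell and 9 did not pass at 24 h in cortex (10 rose and 3 fell adjusted over the list alone; median 0.42, adjusted p = 0.0313, and adjusted p = 0.571 with an estimated correlation). That call was lost without cortex sham replicate 4 (adjusted p = 0.0512) and without cortex 24 h replicate 3 (0.0507) or 4 (0.0892). Vwf, a clotting factor of endothelium, rose 3.57-fold (1.84 ± 0.20, adjusted p = 3.91e-07), and Cldn5, a tight junction protein, 2.05-fold (1.04 ± 0.25, adjusted p = 0.00235). Of 9 mural cell markers, 0 rose, 2 fell and 7 did not pass (1 fell adjusted over the list alone; median -0.04, adjusted p = 0.694, and adjusted p = 0.877 with an estimated correlation). Of 7 oligodendrocyte precursor markers, 1 rose, 4 fell and 2 did not pass (1 rose and 5 fell adjusted over the list alone; median -0.39, adjusted p = 0.17, and adjusted p = 0.619 with an estimated correlation). Of 11 cell division genes, 2 rose, 2 fell and 7 did not pass (3 rose and 2 fell adjusted over the list alone; median 0.03, adjusted p = 0.737, and adjusted p = 0.913 with an estimated correlation). Limma called 3151 genes, 1486 higher and 1665 lower (904 and 2460 with the authors' values), and 2861 had the same direction on 4 of 4 slides. By at least 2-fold 179 were higher and 90 lower (111 and 38 without background correction, 101 and 70 with the authors' values). Without cortex 24 h replicate 1, the array of its group nearest to sham on the second component, 3500 genes were called and 430 at 2-fold or more. With all arrays camera called 10 lists higher and 3 lower, and fry 11 and 4.

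**Figure D3:**
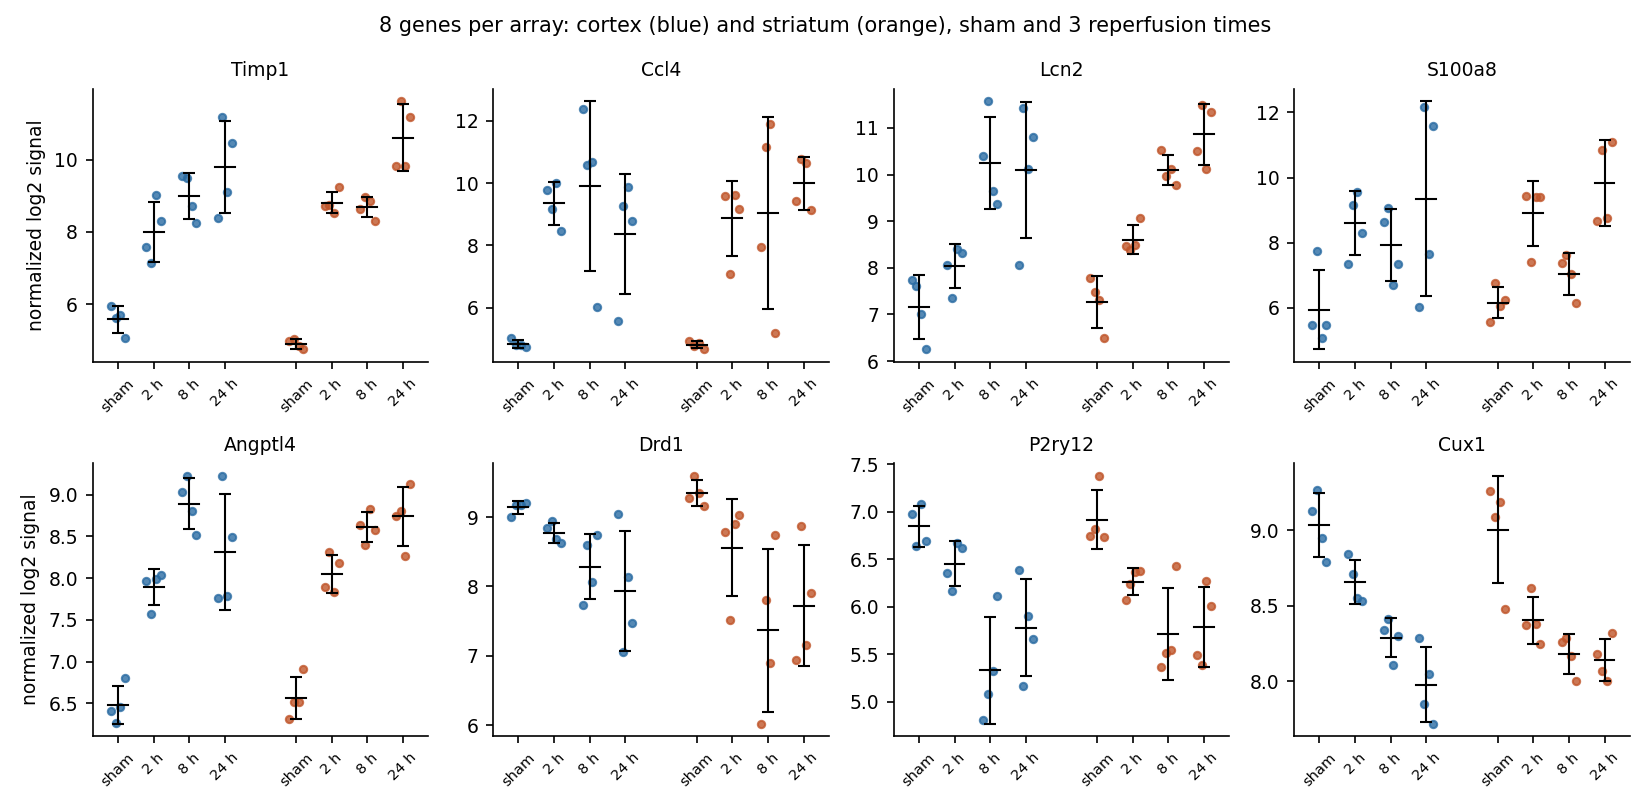
Normalized log2 signal of Timp1, Ccl4, Lcn2, S100a8, Angptl4, Drd1, P2ry12 and Cux1 on each array (dots) with group mean and SD, by time of reperfusion and region (n = 4). Timp1 was 18.4-fold above sham in cortex at 24 h, where 1 of 4 sham arrays detected it, and at least 30.7-fold above it in striatum.

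The steps between times in cortex asked when transcripts moved. From 2 to 8 h Ccl17, a chemokine for T cells, rose 2.84-fold (1.51 ± 0.26, adjusted p = 0.00209) and Tmcc3, an endoplasmic reticulum membrane protein, fell by 1.10 ± 0.22 (adjusted p = 0.00893). Lcn2 rose 4.6-fold (adjusted p = 0.0177), but not without cortex 2 h replicate 2 (adjusted p = 0.0761) or with each region fitted alone (0.0869). Limma called 138 genes higher and 140 lower (250 and 92 with the authors' values), 267 of these 278 in the same direction on 4 of 4 slides. The count was 92, 57 and 95 without 2 h replicates 1, 2 and 3, 167 and 117 without 8 h replicates 1 and 3, 470 without 24 h replicate 1, and 82 with each region fitted alone.

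From 8 to 24 h in cortex Vwf rose 3.2-fold (1.68 ± 0.20, adjusted p = 1.27e-05) and Fcgr4 3.55-fold (1.83 ± 0.32, adjusted p = 0.00119). Depp1 fell by 1.62 ± 0.33 (adjusted p = 0.00414), and Serpina3f, a serine protease inhibitor, fell to a level at least 1.2-fold lower (adjusted p = 0.000147). Limma called 378 genes higher and 390 lower, and 656 of these 768 had the same direction on 4 of 4 slides. Without 8 h replicates 1 and 3 the count was 472 and 331, without 24 h replicates 3 and 4 it was 414 and 314, and with each region fitted alone 448.

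The striatum at 2 h was compared with sham for the earliest response in the deep part of the territory. Timp1 rose at least 8.84-fold (adjusted p = 1.85e-05), Socs3 at least 10.2-fold (adjusted p = 0.000171) and Cxcl1 at least 9.67-fold (adjusted p = 0.00587). Ccn2, a matricellular growth factor, rose 2.36-fold (1.24 ± 0.16, adjusted p = 4.89e-05), and Nfkbia, the inhibitor of NF-kB, 2.51-fold (1.33 ± 0.20, adjusted p = 0.000311). Nkx2-2 fell by 1.72 ± 0.24 (adjusted p = 0.000171) and Hes5, a Notch target, by 1.29 ± 0.27 (adjusted p = 0.00587). The second Nkx2-2 probe fell by 0.52 (adjusted p = 0.0419).

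Of 26 cytokines and chemokines, 8 rose, 0 fell and 18 did not pass in striatum at 2 h (12 rose adjusted over the list alone), with a median of 0.71 and slide medians of 0.40 to 1.06 (adjusted p = 3.33e-06, and adjusted p = 0.525 with an estimated correlation). Ccl7, a monocyte chemoattractant, rose at least 2.78-fold. Of 25 immediate early genes, 6 rose, 0 fell and 19 did not pass (9 rose adjusted over the list alone; median 0.88, adjusted p = 2.96e-05, and adjusted p = 0.571 with an estimated correlation). Of 22 glucocorticoid response genes, 6 rose, 1 fell and 15 did not pass (12 rose and 2 fell adjusted over the list alone; adjusted p = 1.7e-05, and adjusted p = 0.521 with an estimated correlation). Angptl4 rose 2.81-fold. Of 18 cholesterol synthesis genes, 5 rose, 1 fell and 12 did not pass (10 rose and 1 fell adjusted over the list alone; adjusted p = 0.000609, and adjusted p = 0.571 with an estimated correlation). Hmgcs1, an enzyme early in the pathway, rose 1.57-fold. Of 41 respiratory chain subunits, 1 rose, 1 fell and 39 did not pass (1 and 1 adjusted over the list alone), with a median of -0.16 and slide medians of -0.20 to -0.06 (adjusted p = 0.00284, and adjusted p = 0.521 with an estimated correlation).

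Of 18 striatal projection neuron markers, 0 passed at 2 h (0 adjusted over the list alone), with a median of -0.45. Camera called the list lower (adjusted p = 0.00254, and adjusted p = 0.677 with an estimated correlation), but not without striatum 2 h replicate 2 (adjusted p = 0.0955), whose slide median was -1.20. In striatum at 2 h limma called 597 genes, 331 higher and 266 lower (180 and 1091 with the authors' values), 563 of them in the same direction on 4 of 4 slides; 41 were higher and 6 lower by at least 2-fold (28 and 3 without background correction, 24 and 5 with the authors' values). The count was 191, 221, 225 and 957 without sham replicates 1, 2, 3 and 4, and 211, 343 and 262 without 2 h replicates 1, 2 and 3. At 2-fold or more it was 27 and 30 without 2 h replicates 1 and 3. With array weights 2478 genes were called. Camera called 10 lists higher and 3 lower, and fry 6 and 1.

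In striatum at 8 h, compared with sham for the middle phase, some markers of striatal neurons and oligodendrocytes fell. Drd1, a dopamine receptor of striatal projection neurons, fell by 1.99 ± 0.44 (adjusted p = 0.00179), and Nkx2-2 by 2.04 ± 0.24 (adjusted p = 6.36e-06), or by 0.43 on its second probe (adjusted p = 0.0401). Ccl4 rose at least 10.4-fold (adjusted p = 0.00618), or by log2 2.68 on its second probe (adjusted p = 0.0323), Timp1 at least 8.11-fold (adjusted p = 6.36e-06) and Lcn2 7.11-fold (2.83 ± 0.50, adjusted p = 0.000234).

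Of 18 striatal projection neuron markers, 0 rose, 9 fell and 9 did not pass at 8 h (10 fell adjusted over the list alone), with a median of -0.72 and slide medians of -1.46 to 0.16 (adjusted p = 1.7e-05, and adjusted p = 0.591 with an estimated correlation). Of 19 oligodendrocyte and myelin markers, 0 rose, 5 fell and 14 did not pass (6 fell adjusted over the list alone; median -0.15, adjusted p = 0.00704, and adjusted p = 0.598 with an estimated correlation), a call lost with all detected probes (adjusted p = 0.0555). They include Ugt8a and Fa2h, enzymes of myelin lipids, which fell by 0.93 ± 0.15 and 0.99 ± 0.19. Of 22 glucocorticoid response genes, 16 rose, 0 fell and 6 did not pass (16 rose and 1 fell adjusted over the list alone), with a median of 0.74 (adjusted p = 4.21e-08, and adjusted p = 0.465 with an estimated correlation). Of 22 reactive astrocyte genes, 9 rose, 0 fell and 13 did not pass (11 rose adjusted over the list alone; adjusted p = 9.41e-05, and adjusted p = 0.598 with an estimated correlation). Of 25 p53 targets and apoptosis genes, 10 rose, 3 fell and 12 did not pass (13 rose and 3 fell adjusted over the list alone; adjusted p = 0.0151, and adjusted p = 0.521 with an estimated correlation). Apaf1, a part of the apoptosome, rose 2.32-fold. Of the 3 measured lymphocyte markers, too few for a list test, 2 rose, 0 fell and 1 did not pass (2 rose adjusted over the list alone), and Cd3e, part of the T cell receptor complex, rose at least 1.2-fold (adjusted p = 0.000286).

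Limma called 2388 genes in striatum at 8 h, 1171 higher and 1217 lower (543 and 2801 with the authors' values), and 2257 had the same direction on 4 of 4 slides; 92 were higher and 41 lower by at least 2-fold (44 and 13 without background correction, 36 and 36 with the authors' values). Camera called 8 lists higher and 2 lower, and fry 7 and 2.

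At 24 h in striatum, compared with sham for the state a day after occlusion, Timp1 rose at least 30.7-fold (adjusted p = 1.86e-09) and Ccl4 at least 20.1-fold (adjusted p = 0.000812), or by log2 3.19 on its second probe (adjusted p = 0.0087). Ccl12 rose 31.5-fold (log2 4.98 ± 0.65, adjusted p = 3.87e-06), Lgals3 19.1-fold (4.26 ± 0.60, adjusted p = 1.03e-05) and Arg1, an arginase of macrophages, at least 7.88-fold (adjusted p = 7.42e-05). Drd1 fell by 1.63 ± 0.44 (adjusted p = 0.00589), and Gpr6, a receptor of striatal projection neurons, to a level at least 1.53-fold lower (adjusted p = 0.0032). Nefh, a neurofilament subunit, fell by 1.36 ± 0.19 (adjusted p = 6.67e-06).

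Of 22 reactive astrocyte genes, 20 rose, 0 fell and 2 did not pass in striatum at 24 h (20 rose adjusted over the list alone), with a median of 1.95 and slide medians of 1.20 to 2.82 (adjusted p = 4.94e-14, and adjusted p = 0.521 with an estimated correlation). Of 26 matrix remodelling and wound genes, 22 rose, 2 fell and 2 did not pass (22 rose and 3 fell adjusted over the list alone; median 1.29, adjusted p = 2.16e-11, and adjusted p = 0.521 with an estimated correlation). Of 17 interferon-stimulated genes, 14 rose, 0 fell and 3 did not pass (15 rose adjusted over the list alone; median 1.14, adjusted p = 1.49e-08, and adjusted p = 0.521 with an estimated correlation). Ifitm3 rose 4.04-fold and Usp18, which removes ISG15 from proteins, at least 2.98-fold. Of 13 neutrophil and monocyte markers, 10 rose, 0 fell and 3 did not pass (11 rose adjusted over the list alone; median 1.80, adjusted p = 2.61e-06, and adjusted p = 0.521 with an estimated correlation). S100a8 rose 12.7-fold. Of 21 endothelial and blood-brain barrier markers, 11 rose, 1 fell and 9 did not pass (11 rose and 1 fell adjusted over the list alone; median 0.50, adjusted p = 0.000992, and adjusted p = 0.521 with an estimated correlation). Of 16 meningeal and fibroblast markers, 6 rose, 0 fell and 10 did not pass (6 rose and 2 fell adjusted over the list alone; median 0.31, adjusted p = 0.0385, and adjusted p = 0.571 with an estimated correlation). That call was lost without striatum sham replicate 3 (adjusted p = 0.0848) or 4 (0.0717), without striatum 24 h replicate 2 (0.0616) or 4 (0.0718), and with array weights (0.0534).

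Of 18 striatal projection neuron markers, 0 rose, 12 fell and 6 did not pass at 24 h (14 fell adjusted over the list alone; median -0.94, adjusted p = 1.94e-05, and adjusted p = 0.591 with an estimated correlation). Of 18 astrocyte markers, 0 rose, 7 fell and 11 did not pass (8 fell adjusted over the list alone; median -0.33, adjusted p = 0.014, and adjusted p = 0.521 with an estimated correlation), among them Gjb6, a gap junction protein (-0.72 ± 0.14). Of 34 ion channel and neurotransmitter receptor genes, 2 rose, 9 fell and 23 did not pass (2 rose and 9 fell adjusted over the list alone; median -0.31, adjusted p = 0.00485, and adjusted p = 0.571 with an estimated correlation). Of 13 choroid plexus and ependyma markers, 0 passed (0 adjusted over the list alone; median 0.32, adjusted p = 0.329, and adjusted p = 0.877 with an estimated correlation), though the list passed without striatum 24 h replicate 3 (adjusted p = 0.0257) and with the authors' values (0.04). Limma called 2931 genes, 1396 higher and 1535 lower (726 and 3495 with the authors' values), and 2646 had the same direction on 4 of 4 slides. At 2-fold or more, 293 were higher and 65 lower (185 and 15 without background correction, 141 and 55 with the authors' values). Camera called 13 lists higher and 4 lower, and fry 13 and 5.

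**Figure D4:**
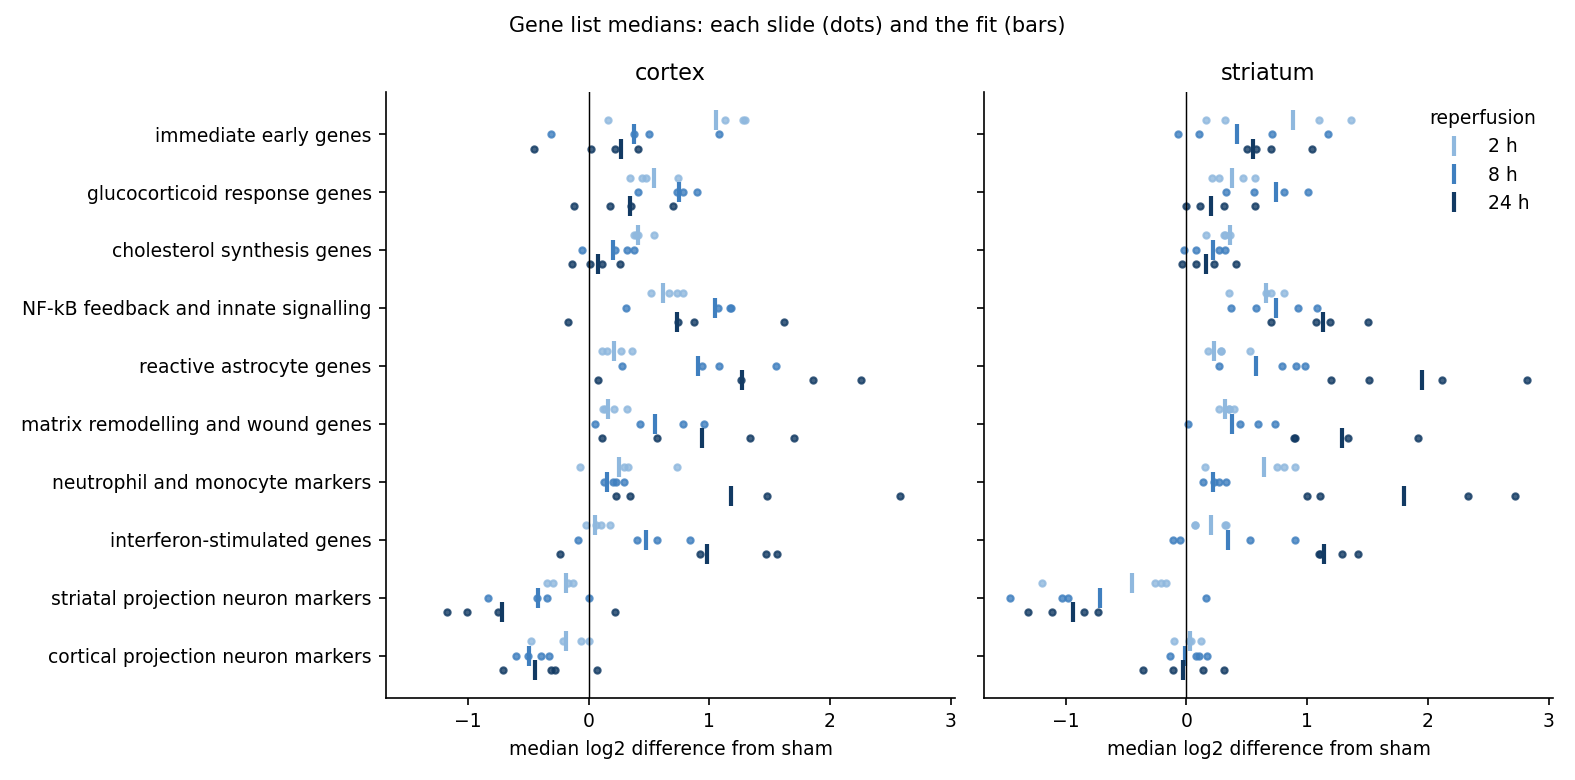
Median log2 change against sham of 10 gene lists at 2, 8 and 24 h in cortex and striatum, with 1 dot per slide (reperfusion array minus the sham array of that slide, 4 slides per region) and a bar for the median over the fitted changes. Reactive astrocyte genes reached 1.27 in cortex and 1.95 in striatum at 24 h, and striatal projection neuron markers -0.94 in striatum.

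Between 2 and 8 h in striatum, where the question was again when transcripts moved, Pnpla2, a lipase of fat droplets, rose 2.3-fold (1.20 ± 0.19, adjusted p = 0.00113) and Lrg1, a glycoprotein of inflammation, 2.72-fold (1.44 ± 0.29, adjusted p = 0.0126). Ugt8a fell by 0.99 ± 0.15 (adjusted p = 0.000997). Limma called 68 genes higher and 77 lower (35 and 120 with the authors' values), 144 of these 145 in the same direction on 4 of 4 slides. The count was 28, 82, 34 and 71 without 2 h replicates 1, 2, 3 and 4, 69 and 68 without 8 h replicates 3 and 4, 250 with the slide as a block, 95 with each region fitted alone and 383 with array weights.

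Between 8 and 24 h in striatum Arg1 rose at least 7.29-fold (adjusted p = 0.000367), Tgm1, a crosslinking transglutaminase, at least 5.16-fold (adjusted p = 1.1e-05), and Ccl12 10.6-fold (3.40 ± 0.65, adjusted p = 0.00122). The lowest changes included Tph2, which makes serotonin (-2.45 ± 0.49, adjusted p = 0.00179), Slc6a4, the serotonin transporter (-2.10 ± 0.38, adjusted p = 0.000852, detected on 1 of 4 arrays at 24 h), and Ucn, the neuropeptide urocortin, which fell to a level at least 2.42-fold lower (adjusted p = 3.16e-05). Tph2 and Slc6a4 are transcribed in neurons of the raphe in the brainstem, and Tph2 spanned 2.39 log2 units over the 4 striatum sham arrays. Limma called 444 genes higher and 302 lower, 708 of these 746 in the same direction on 4 of 4 slides. Without 8 h replicate 4 the count was 438, without 24 h replicate 2 it was 325, and with array weights 434.

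The responses of the regions were compared to learn whether cortex and striatum reacted differently. At 24 h 6 genes passed this test. Sla, an adaptor protein of immune receptor signalling, changed by 1.72 in striatum and 0.40 in cortex, a difference of 1.31 ± 0.26 (adjusted p = 0.0449). Glra1, a glycine receptor subunit of brainstem and spinal cord, passed too (adjusted p = 0.0208), but its fitted difference of -1.31 rests on levels at background. It was detected on 0 of 4 striatum arrays at 24 h, to a level at least 1.64-fold lower than in sham, and on 0 arrays of both cortex groups, where a fall could not be seen, so no difference between the regions is shown for it. It is 1 of 16 midbrain and brainstem markers chosen after the data were seen, of which 7 were lower and 0 higher in striatum at 24 h than in sham (6 and 0 of the other 15). Nrcam, a neuronal adhesion molecule, differed by 0.53 ± 0.11, Fam199x by -1.07 ± 0.21, Ankrd35 by -0.85 ± 0.17 and Cdc37l1, a cochaperone, by -0.60 ± 0.12 (adjusted p = 0.0449 each). Fam199x was detected on 2 of 4 striatum arrays at 24 h, so its difference rests in part on background. The other 3 detected probes of Cdc37l1 differed by -0.44, -0.08 and 0.08 (adjusted p = 0.608, 0.929 and 0.955), and among all probes the one used had adjusted p = 0.0634. With the slide as a block Sla and Nrcam had adjusted p = 0.0748, Fam199x 0.0706 and Cdc37l1 0.0714.

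Limma found 0 genes whose response differed at 2 h and 0 at 8 h (607 and 748 at an unadjusted p under 0.05, with smallest adjusted p = 0.233 and 0.087), and 6 at 24 h. At 2 h array weights gave 55 genes, the authors' values 1 and pairing same-numbered arrays as one animal 2. At 8 h 75th percentile scaling gave 1, the slide as a block 2 and the animal pairing 14, and leaving out 1 array gave 0 to 9 (9 without cortex 8 h replicate 4). At 24 h the count was 0 without cortex sham replicate 1 or 4, cortex 24 h replicate 4, or striatum 24 h replicate 2 or 4, and without background correction. It was 1 without cortex 2 h replicate 1, cortex 8 h replicate 1, 2, 3 or 4, cortex 24 h replicate 3, striatum sham replicate 1, striatum 2 h replicate 1, 2 or 3, or striatum 8 h replicate 2 or 3. It was 2 without cortex sham replicate 3, cortex 24 h replicate 2, or striatum sham replicate 2 or 3, 3 without cortex 24 h replicate 1 and with the slide as a block, 28 with the animal pairing and 61 with array weights.

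Among lists, oligodendrocyte and myelin markers had lower changes in striatum than in cortex at 2 h (median difference -0.40, adjusted p = 6.3e-09, and adjusted p = 0.313 with an estimated correlation) and at 8 h (-0.42, adjusted p = 6.3e-09, and adjusted p = 0.313 with an estimated correlation). Of the 19 markers, 0 passed alone at either time, and 2 and 4 were lower adjusted over the list alone. Cortical projection neuron markers had higher changes in striatum at 8 h (0.50, adjusted p = 6.91e-05, and adjusted p = 0.313 with an estimated correlation), with 3 of 18 higher adjusted over the list alone. Their median change in cortex was -0.49, and 15 of 18 were already lower in sham striatum than in sham cortex (median -1.36). A fall in striatum could thus be harder to see, so a weaker response there is not shown. Fry called 0 lists for the region differences.

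Of the genes called in either region, 93.7%, 94.5% and 93.6% at 2, 8 and 24 h had changes of the same sign in both, against 70.4%, 75.6% and 78.9% of all genes. At 2, 8 and 24 h, 78, 536 and 966 genes were higher in both regions (7.3, 112.2 and 218.9 by chance), 52, 556 and 968 were lower in both (6.5, 129.6 and 269.7 by chance), and 0, 4 and 4 had opposite calls (14, 241.3 and 486.1 by chance). Across 9475 genes, which are not independent replicates, Pearson's r between the changes in cortex and striatum was 0.68, 0.75 and 0.84, and Spearman's rho 0.56, 0.69 and 0.77. The counts by chance take the regions as independent, whereas cortex and striatum arrays of the same time and number varied together (mean r 0.21 over 16 pairs). How much this raised the overlap, the shared signs and r was not tested. In sham, striatal projection neuron markers hardly differed between the regions (median 0.27, 2 of 18 higher in striatum), whereas 15 of 18 cortical projection neuron markers were lower in striatum (median -1.36). Whether samples of both regions held some of the same tissue, which would also raise the agreement, was not tested.

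**Figure D5:**
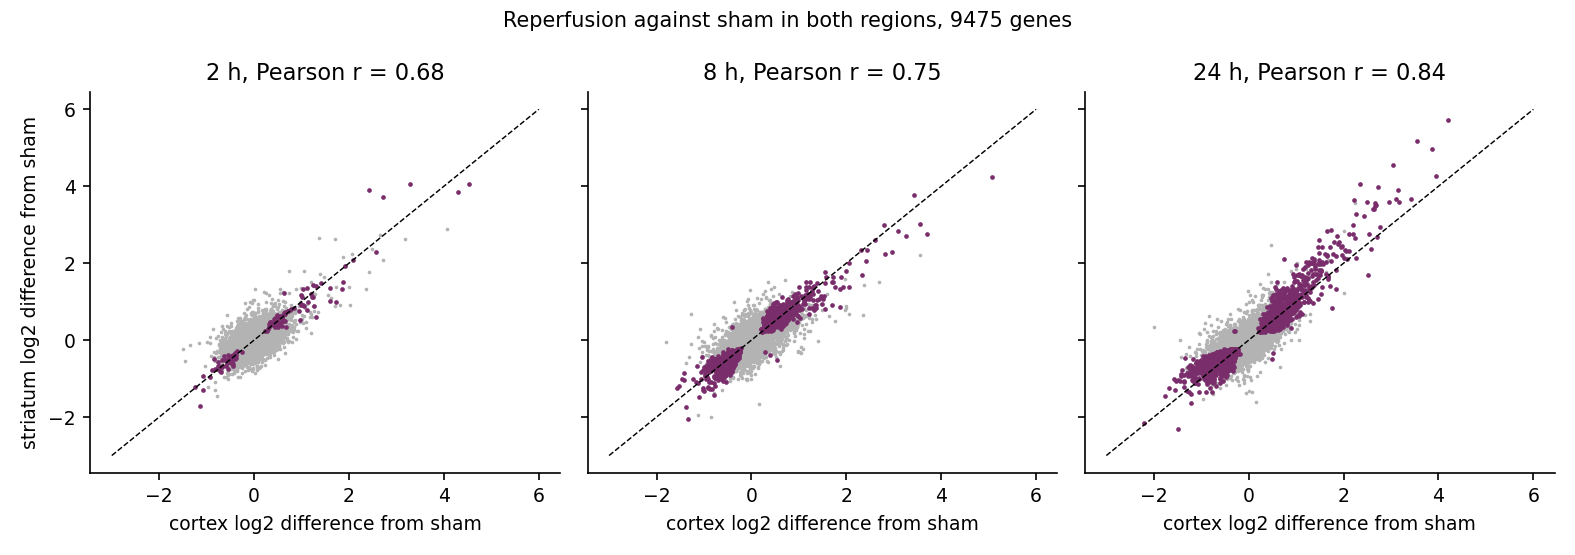
Log2 change against sham of each gene in cortex (horizontal) and striatum (vertical) at 2, 8 and 24 h, with genes that passed in both regions in purple. Pearson's r across genes was 0.68, 0.75 and 0.84.

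The sham arrays of the regions were compared to see what each sample held before injury. The genes in this paragraph were chosen after their values were seen. Tbr1 and Fezf2, transcription factors of deep-layer cortical neurons, were lower in striatum by log2 -3.55 (adjusted p = 5.58e-11) and -3.15 (adjusted p = 5.96e-09), and Slc17a7, the vesicular glutamate transporter of cortex, by -2.93 (adjusted p = 2.39e-10), with n = 4 arrays per region. Of 18 cortical projection neuron markers, 15 were lower, with a median of -1.36. Of 18 striatal projection neuron markers, 2 were higher in striatum, Tac1, the precursor of substance P (0.87, adjusted p = 0.0362), and Scn4b, a sodium channel subunit (0.77, adjusted p = 0.0377), with a list median of 0.27. The cortex sham mean of Drd1 was 9.15 against 9.35 in striatum (difference 0.20, adjusted p = 0.762). Pmch, a hypothalamic neuropeptide precursor, was higher in striatum by 6.80 (adjusted p = 2.39e-10, detected on 1 of 4 cortex arrays) and Slc17a6, the vesicular glutamate transporter of thalamus, by 2.64 (adjusted p = 7.39e-13). Limma called 3219 genes, 1644 higher and 1575 lower in striatum. Each region lay on its own 4 slides, so region and slide set cannot be told apart.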

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

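All tests in this part of explanations for a pattern were chosen after the pattern was seen; the region differences, time steps and searches for arrays far from their group were planned.

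Gpx1, the gene of the knockout label, gave a signal on every array. A signal at the array background is argued against, since the probe was detected on 32 of 32 arrays and its group means lay at the 85th to 91.3th percentile of probes. A probe outside the part of the gene that a knockout deletes may account for it, because a knockout allele can still be transcribed; only 1 probe was on the array, so no second probe could be compared. A wrong genotype label also stays open, as the growth protocol names male wild-type mice where all other labels say Gpx1 knockout, and no wild-type array was there to set the level. The rise in cortex at 8 h (0.88) was not explained by any test here.

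Transcripts of hypothalamus, thalamus and midbrain were high in sham striatum, with Pmch at a mean log2 signal of 12.07 in striatum against 5.27 in cortex. Tissue from beyond the striatum in the striatum samples is a candidate explanation. Of 39 measured markers of those places, written down before their values were seen except for Glra1, which the region test had already named, 37 were higher in sham striatum than in sham cortex and 2 lower (Nr4a2 -1.47, and Lhx2, detected on 0 striatum sham arrays), with a median of 1.91 (1.89 without Glra1), or 1.56 with undetected groups at the floor (camera p = 3.37e-27, and p = 3.6e-05 with an estimated correlation). However, 16 of the 39 were detected on all 4 cortex sham arrays and 4 belonged to a fixed list. The highest signals, which do not rank transcripts by amount, were Slc17a6 (12.70) and Calb2 (12.02), and 11 further markers, among them Oxt, Slc6a3 and Hcrt (at least 16.2-, 14.9- and 8.71-fold higher), had been seen before. An exchange of the region labels is argued against, since cortical projection neuron markers had a median of -1.36 in striatum against cortex. Striatal projection neuron markers hardly parted the regions (median 0.27, 2 of 18 higher in striatum), so they add little to this. A difference between the slide sets is argued against for these markers as a set, although 0 slides held both regions. Their median lay 1.90 above that of genes of like mean signal. Among 10000 sets, the markers' own included, the other sets, drawn from such genes, had medians of at most 0.28. Those genes passed the same filter but were not matched for the region in which they were detected. A marker ranged over the 4 sham slides by a median of 0.65 in striatum and 0.35 in cortex. For single genes it stays open. Of the cortex arrays, 8 h replicate 2 read Pmch at 9.71 and Hcrt at 7.78, which shows that cortex slides can report these genes. Over 23 hypothalamus and thalamus markers not seen before it lay a median of 0.49 above the other arrays of its group, with 3 over 2-fold, and over 16 midbrain and brainstem markers at -0.03. Cortex 2 h replicate 1 had 5 of the 23 over 2-fold and a median of 0.34. Whether tissue from beyond the cortex entered these samples was not tested.

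Tph2 and Slc6a4 fell in striatum from 8 to 24 h (-2.45 and -2.10, Slc6a4 detected on 1 of 4 arrays at 24 h), and Ucn fell to a level at least 2.42-fold lower. A smaller share of midbrain and brainstem tissue in the 24 h samples could account for this, but 16 other markers of those places had a median of -0.20 (camera p = 0.0499, and p = 0.268 with an estimated correlation), with 1 passing lower and 0 higher, which leaves it open. That one was Glra1, detected on 0 striatum arrays at 24 h and already named by the region test. The other 15 had a median of -0.20 (camera p = 0.119, and p = 0.365 with an estimated correlation) and 0 passed. Against sham these 16 markers had medians of -0.26, -0.36 and -0.46 at 2, 8 and 24 h, with 1, 5 and 7 passing lower and 0 higher (at 24 h camera p = 0.00161, and p = 0.0807 with an estimated correlation). Without Glra1 the median at 24 h was -0.43, with 6 lower and 0 higher (camera p = 0.00799, and p = 0.129 with an estimated correlation). Less of this tissue in the 24 h than in the sham samples thus stays open too. The 23 markers of hypothalamus and thalamus had a median of -0.05 from 8 to 24 h, and of -0.29 at 24 h against sham (3 lower, 1 higher). A response of serotonin neurons to reperfusion stays open too, since Tph2 already spanned 2.39 log2 units over the 4 sham arrays (9.68, 7.60, 9.99 and 7.99) and was 5.11, 7.18, 9.22 and 7.27 at 24 h. On the same sham arrays Slc6a4 read 7.87, 5.84, 8.15 and 6.20, and Ucn 6.33, 4.68, 6.60 and 5.31 (detected on 2 of 4). These genes thus varied together without reperfusion.

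Some arrays stood apart within their group of 4, with a gap to the nearest array, as a share of the group's range, above Dixon's 95% critical value. This held for 3 of 48 groups of array measures (the PC1 score of striatum sham replicate 1, 25.7; the mean Pearson's r of striatum sham replicate 4 with its group, 0.9881; Gpx1 in striatum 24 h replicate 2, 9.93) and for 7 of 186 groups of list medians. Chance gives about 1 in 20 groups. The list medians were immediate early genes 0.16 in cortex 2 h replicate 4, cholesterol synthesis genes 0.54 in cortex 2 h replicate 3, NF-kB feedback and innate signalling 0.31 in cortex 8 h replicate 4, striatal projection neuron markers -1.20 and endothelial activation and adhesion 0.67 in striatum 2 h replicate 2, meningeal and fibroblast markers 0.06 in striatum 24 h replicate 1, and choroid plexus and ependyma markers -0.36 in striatum 24 h replicate 3.

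The test of a difference between regions at 24 h, as striatum minus cortex, passed for Sla (1.31), Nrcam (0.53), Cdc37l1 (-0.60), Ankrd35 (-0.85) and Fam199x (-1.07, detected on 2 of 4 striatum arrays at 24 h). With the slide as a block Sla and Nrcam (adjusted p = 0.0748), Fam199x (0.0706) and Cdc37l1 (0.0714) did not pass. No gene passed without cortex sham replicate 1 or 4, cortex 24 h replicate 4, or striatum 24 h replicate 2 or 4 (0 genes each), or without background correction (0). Chance was not excluded for these genes, as given below. Glra1 passed the same test (-1.31), but with 0 arrays detected in striatum at 24 h and in both cortex groups it shows no difference in response. Of 4 detected Cdc37l1 probes, 2 differed by -0.08 and 0.08. By camera with the preset correlation, list medians differed at 2 h for immediate early genes (-0.29), astrocyte (-0.13), striatal projection neuron (-0.23), oligodendrocyte and myelin (-0.40), endothelial and blood-brain barrier (-0.16) and meningeal and fibroblast markers (0.25) and cholesterol synthesis genes (-0.15). At 8 h they differed for heat shock proteins and cochaperones (-0.23) and striatal projection neuron (-0.40), cortical projection neuron (0.50), oligodendrocyte and myelin (-0.42) and meningeal and fibroblast markers (0.44). At 24 h they differed for immediate early genes (0.53), cytokines and chemokines (0.37), NF-kB feedback and innate signalling (0.29), interferon-stimulated genes (0.45), microglia markers (0.36), reactive astrocyte genes (0.51), astrocyte (-0.18), striatal projection neuron (-0.41), cortical projection neuron (0.29), oligodendrocyte and myelin (-0.20) and meningeal and fibroblast markers (0.43), and matrix remodelling and wound genes (0.50). None of these lists passed with an estimated correlation (smallest adjusted p = 0.313) or by fry. Of the 18 cortical projection neuron markers, 15 were already lower in sham striatum than in sham cortex, so a fall in striatum could be harder to see. With the slide as a block, striatal projection neuron markers at 2 h (adjusted p = 0.0560) and cytokines at 24 h (adjusted p = 0.0634) did not pass. Without cortex 24 h replicate 1 the 24 h medians were -0.01 for NF-kB (adjusted p = 0.678), 0.11 for interferon-stimulated genes (0.821), 0.04 for reactive astrocyte genes (0.85) and 0.19 for matrix genes (0.299).

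The time steps changed 278 and 768 genes in cortex (8 h against 2 h, 24 h against 8 h) and 145 and 746 in striatum. All 35 splits of 8 arrays were refitted, and for every comparison with sham only 1 split, the real one, gave as many genes. In cortex at 2, 8 and 24 h the counts were 441, 1917 and 3151 (highest other 7, 5 and 1231). In striatum they were 597, 2388 and 2931 (highest other 2, 917 and 457). The same held at 2-fold or more, where 1 split of 35 was as large in each comparison (cortex 51, 150 and 269, highest other 3, 2 and 155; striatum 47, 133 and 358, highest other 1, 29 and 29). It held too for the steps of 278, 145 and 746 genes (1 of 35 each, highest other 34, 12 and 18), and for sham striatum against sham cortex (1 of 35, 3219, highest other 6). These shares argue against chance only if arrays are exchangeable across slides. Within a region, arrays of a slide were not shown to vary independently, and in cortex they varied together (median r 0.15, 18 of 24 pairs above 0.1). Only 8 of the 35 splits part every slide, too few for a share under 0.05, so with the slide kept chance was not excluded. Among these 8 the highest other was 1, 1 and 723 genes in cortex at 2, 8 and 24 h and 2, 5 and 457 in striatum. In the step from 8 to 24 h in cortex, chance was not excluded even with arrays exchangeable across slides, as 2 of 35 splits were as large (768, highest other 796). The other exchanged cortex 8 h replicate 4 with cortex 24 h replicate 2, and among the 8 splits that part every slide the highest other was 350.

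For counts of lists called by camera, chance was not excluded in any comparison with sham: 3, 5 and 18 of 35 splits were as large in cortex at 2, 8 and 24 h (12, 16 and 13 lists, highest other 13, 19 and 19). In striatum it was 3, 12 and 6 of 35 (13, 10 and 17, highest other 16, 15 and 20). For the region differences, 100 splits of the arrays decided nothing. With 0 genes at 2 and 8 h all 100 splits were as large by construction (highest other 4 and 79), and splits that turn the labels of one region make the shared response into a difference (at 24 h 8 as large as 6 genes, highest other 683; lists 45, 76 and 44 as large as 7, 5 and 12, highest other 15, 17 and 20). Whole slides were therefore exchanged between regions in 35 splits, with the slide as a block, and chance was not excluded. At 8 and 24 h 2 and 3 splits were as large (2 and 3 genes, highest other 7 and 37). At 2 h the real count was 0 and all 35 were as large. This exchange takes the 8 slides as unrelated, whereas cortex and striatum arrays of the same time and number varied together (mean r 0.21 over 16 pairs), and with these as one animal 2, 14 and 28 genes differed at 2, 8 and 24 h. If they share an animal, only the 8 splits that part the slides of every number hold, too few for a share under 0.05, and among these the highest other was 0 genes at 8 and at 24 h. The exchange therefore leaves the paired counts undecided. For lists 6, 18 and 17 of the 35 splits were as large at 2, 8 and 24 h (6, 6 and 11 lists, highest other 9, 14 and 19).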

How the results depend on the processing

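The fry test was chosen after the result was seen; all other settings in this part were planned. Of 297 results for single genes, 277 passed; 240 of these kept direction and threshold in every planned setting that refits all arrays and 212 in every fit without 1 array. Of 279 list results, 105 passed, with 88 and 72 kept, the estimated correlation aside. None reversed. No filter on detection cost 24 gene calls and each region alone 20. With the authors' values the median change of all genes was -0.133, -0.095 and -0.09 in cortex at 2, 8 and 24 h, against -0.013, -0.015 and -0.011 in the main fit. In striatum it was -0.088, -0.133 and -0.177, against 0.001, -0.007 and -0.026. These medians were not subtracted, so the changes and counts given with the authors' values include this shift. Signal over background limited Glra1, which was not above background in cortex, and Fam199x, detected on 2 of 4 striatum arrays at 24 h. Where no cause is given below, the cause was not tested.

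With the authors' values 2008 genes changed in cortex and 1271 in striatum at 2 h, 1 differed between regions at 2 h, and 78 and 171 changed at least 2-fold in cortex at 8 and 24 h and 29, 72 and 196 in striatum at 2, 8 and 24 h. Array weights gave 1660 genes in cortex and 2478 in striatum at 2 h (77 and 78 at 2-fold or more), 383 and 434 for the striatum steps, and 55 and 61 region differences at 2 and 24 h. Without background correction 31, 82 and 149 genes in cortex and 31, 57 and 200 in striatum changed at least 2-fold, and 0 differed between regions at 24 h. Each region normalized and fitted alone gave 209 genes in cortex at 2 h, 82 and 448 for the cortex steps and 95 for striatum 8 h against 2 h. This setting changed the normalization and the arrays behind the spread at once, so their effects cannot be told apart. The slide as a block gave 250 for striatum 8 h against 2 h and 2 and 3 region differences at 8 and 24 h. Same-numbered arrays as one animal gave 2, 14 and 28 region differences, 75th percentile scaling 1 at 8 h and all detected probes 1 at 24 h. Camera with an estimated correlation called 0 lists in all 6 comparisons with sham and all 3 region differences; fry called 7 in cortex and 7 in striatum at 2 h and 0, 0 and 0 for the regions.

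Leaving out 1 array gave 173 to 545 genes in cortex at 2 h (210, 211, 283 and 290 without sham replicates 1, 2, 3 and 4, 173 and 174 without 2 h replicates 2 and 3) and 1148 to 2080 at 8 h (1148 without sham replicate 2, 1164 without 8 h replicate 3). In striatum at 2 h it gave 191 to 957 (191, 221, 225 and 957 without sham replicates 1, 2, 3 and 4, 211, 343 and 262 without 2 h replicates 1, 2 and 3). For cortex 8 h against 2 h it gave 57 to 470 (92, 57 and 95 without 2 h replicates 1, 2 and 3, 167 and 117 without 8 h replicates 1 and 3, 470 without 24 h replicate 1), and for 24 h against 8 h 314 to 1146 (472 and 331 without 8 h replicates 1 and 3, 414 and 314 without 24 h replicates 3 and 4). For striatum 8 h against 2 h it gave 28 to 215 (28, 82, 34 and 71 without 2 h replicates 1, 2, 3 and 4, 69 and 68 without 8 h replicates 3 and 4), and for 24 h against 8 h 325 to 844 (438 without 8 h replicate 4, 325 without 24 h replicate 2). Region differences ranged from 0 to 0 at 2 h, 0 to 9 at 8 h (9 without cortex 8 h replicate 4, 3 without striatum 8 h replicate 2, 2 without striatum sham replicate 4, and 1 without cortex 2 h replicate 1, striatum sham replicate 3 or striatum 8 h replicate 4) and 0 to 8 at 24 h, where 22 of 32 arrays lowered 6 to between 0 and 3. Counts at 2-fold or more ranged from 117 to 233 in cortex at 8 h (233 without 8 h replicate 4), 184 to 430 at 24 h (430 without 24 h replicate 1) and 27 to 59 in striatum at 2 h (27 and 30 without 2 h replicates 1 and 3). Lists called ranged from 10 to 17 in cortex at 8 h (10 without 8 h replicate 1), and for the regions from 3 to 9 at 2 h (3 without striatum sham replicate 4), 5 to 9 at 8 h (9 without cortex 8 h replicate 4) and 7 to 17 at 24 h (7 without cortex 24 h replicate 1 or striatum 24 h replicate 2). The other comparisons moved by less than 1.5 times, with 2375 to 3500 genes in cortex at 24 h, 1618 to 2568 and 2185 to 3042 in striatum at 8 and 24 h, and 2748 to 3317 between sham regions.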

Other observations

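The test of shared numbers between regions was chosen after the data were seen; the values within a region follow a planned check. Each array's departure from its group mean was correlated, across genes, with that of other arrays. Cortex and striatum arrays of the same time and number had a mean Pearson's r of 0.21 (-0.05 to 0.56, 16 pairs), against 0.06 for the same number at another time (48 pairs) and -0.07 for the same time with another number (48 pairs). Departures within a group sum to 0, so the value for another number follows in part from that for the same number and is no separate contrast. A permutation test of the numbers gave p = 0.00013 (100000 permutations, one-sided). The consensus correlation of such pairs was 0.228. The labels do not say whether the regions came from the same animals.

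Within cortex, arrays of the same number, which share a slide, had a median r of 0.15 (-0.27 to 0.35, 18 of 24 pairs above 0.1), against -0.06 for other numbers. Within striatum the median was 0.06 (-0.27 to 0.33, 9 of 24 pairs above 0.1), against -0.04. Here too the values for other numbers follow in part from those for the same number. On the second principal component, striatum 8 h replicate 4 lay at -5.3.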
